A study of Mus musculus with 36 samples.

How the data were processed

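The series measured messenger RNA of the renal cortex of male mice on the C57BLKS/J background in 2 arms, m/m mice (Control) and db/db mice (Diabetes), at 6 zeitgeber times 4 h apart (ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20; ZT0 is lights on). Each of the 12 groups held 3 libraries, 36 in all. Per the labels' protocols, total RNA was isolated with a mirVana kit and libraries were made with a TruSeq Stranded mRNA kit. The db allele lies in Lepr, the leptin receptor gene. The labels do not say in words that the 3 libraries of a group came from separate animals.

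The authors deposited FPKM values (fragments per kilobase of gene scaled to library size) for 22173 genes, in 1 table per arm, and the submitters' processing notes name Trimmomatic, Cufflinks and HTSeq with no version. The aligner, the genome build and the annotation are not given in the sources used here. Depth was estimated from the low values, where most of a gene's values are near whole multiples of what 1 fragment is worth. The values put each library at 14.9 to 17.5 M fragments (median 16.4). The arms had 16.6 ± 0.52 M in control and 16.1 ± 0.64 M in diabetes (mean ± SD, n = 18). The absolute scale rests on 254 of 2722 genes with such a step and a length in GENCODE M21. These are the genes whose lengths give the most common depth. The other genes with a length gave other depths, so the absolute depth is an estimate. Within a tolerance of 0.05, 78.7% of the low values of the control table and 78.5% of those of the diabetes table were whole multiples of the gene's smallest value, where chance gives 10%. At this depth 1 fragment in a gene of 1 kb is worth 0.0572 to 0.0671 FPKM, which limits what can be said of genes far below the filter. Of the 36 pairs of replicates none differed as little as sampling noise: the smallest mean chi-square per gene was 9.79. All columns were mapped to a library (0 left over).

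Tests were made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), for the 11088 genes with a mean FPKM of at least 1 over the 36 libraries; fold changes are on that scale, which understates the change of low genes. The arms were compared over all times with time as a 6-level factor, and at each time as a contrast of the group means in 1 fit of all 36 libraries, with a trend in the prior variance. Rhythm was tested in each arm of 18 libraries by an F test of a 24-h cosinor, whose amplitude is measured from the mean to the peak on the log2 scale, and the difference in rhythm by an F test of the interaction of arm with the cosine and sine terms. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were compared by camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry; the share of rhythmic members was tested by the two-sided Fisher's exact test over 102 pairs of list and gene set. Peak times and amplitudes of the clock genes were compared by two-sided permutation tests that exchanged the arms within each time, with 100000 draws. The adjusted p-values of single genes below are limma's.

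The design, the tests, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took Lepr; the 10 genes with the largest change in each direction over all times, with a mean of at least 5 FPKM and the same sign at all 6 times; the 2 largest in each direction at each time; the 6 largest amplitudes in each arm; every gene of the clock list; the genes whose rhythm differed, up to 8 with a lower and 8 with a higher amplitude in diabetes; and 2 to 4 members of each list with the smallest adjusted p. It passed over 2 predicted gene models, and some of the genes it took are not reported here. Of the 35 lists, 34 had tested members and the lymphocyte list had 0. Beside the clock list they cover fatty acid oxidation, PPAR-alpha targets and ketogenesis, fatty acid synthesis, cholesterol synthesis, fatty acid uptake and triglyceride turnover, cholesterol and lipoprotein transport, sphingolipids and phospholipids, gluconeogenesis, glycolysis, oxidative phosphorylation, markers of nephron segments and of other cell types, tubule injury, extracellular matrix, inflammation, interferon, antioxidant response, renin-angiotensin, heat shock, glucocorticoid response, immediate early genes, unfolded protein response, sex-dependent kidney genes and the cell cycle. Some genes stand in 2 lists, such as Cyp4a14 (PPAR-alpha and female kidney) and Acsm3 (fatty acid uptake and male kidney). The cell type lists give levels of marker genes in bulk tissue, not shares of cells.

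The steps were tested on simulated data of 11088 genes. Of 50 genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, the comparison over all times found 39, 48, 49 and 50, with 10 false calls; at ZT0 it found 4, 30, 45 and 50, with 5 false calls. For amplitudes of the same sizes the test in control found 41, 48, 50 and 50, that in diabetes 35, 47, 50 and 50, and the test of a difference in rhythm 29, 48, 48 and 50. A list of 15 genes moved by 0.25 was called and 0 other lists were. The simulated genes varied independently and with the same spread in both arms, so lists whose members vary together were not tested. In the data the estimated correlation within a list reached 0.74 (oxidative phosphorylation).

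The alternatives were pseudocounts of 0.1 and 1, no filter and a minimum mean of 5 FPKM, median-ratio scaling and quantile normalization, the replicate number as a block, array weights, an added minimum log2 fold change of 1 or amplitude of 0.25, the 6 libraries of a time alone, time as a 6-level factor, an adjustment over rhythmic genes, an estimated correlation, and leaving out each library in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for depth and figures. Positions by chromosome come from the RefSeq annotation of GRCm38.p6, in which 99.9% of the tested symbols were found; no coordinates are given, since the authors' build is not known here.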

Results

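Gene expression was measured in the renal cortex of db/db mice, a model of type 2 diabetes with a defect in the leptin receptor, and of m/m controls, every 4 h over 1 day. The title of the series asks how the circadian program of lipid metabolism differs in early diabetic kidney disease. There were 18 libraries per arm, 3 at each of 6 times, at an estimated 14.9 to 17.5 M fragments each. Values per arm are FPKM as mean ± SD over the 18 libraries, so that the SD includes the change over the day; values per group have n = 3. Fold changes are log2, diabetes minus control, on log2(FPKM + 0.5), with their standard error.

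Lepr, the gene of the db allele, was looked at first. It stood at 0.710 ± 0.261 FPKM in control and 0.672 ± 0.278 in diabetes (n = 18; permutation p = 0.61), below the filter, so that its level did not separate the arms at this depth. Gene-level FPKM does not show the allele itself. Nothing in the labels says that the 3 libraries of a group are separate animals, so the p-values measure the spread between these samples.

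The first comparison asks which genes differ between the arms over the whole day. A gene of fatty acid hydroxylation showed the largest gain. Cyp4a14, a fatty acid omega-hydroxylase, rose from 4.64 ± 2.11 to 235 ± 63.0 FPKM (5.58 ± 0.15; adjusted p = 4.3e-25). The glucuronosyltransferase genes Ugt1a2 (5.25 ± 0.20) and Ugt1a10 (3.33 ± 0.13) rose as well, but their transcripts share exons, so reads could be split between them; the same holds for Cyp4a14, Gsta2 and Slc22a26, which have close paralogs. Bhmt, a methyltransferase that uses betaine, rose by 3.67 ± 0.14, Gc, the vitamin D-binding protein, by 3.66 ± 0.13, Gsta2, a glutathione transferase, by 3.39 ± 0.35, and Cyp27b1, which makes active vitamin D, by 3.01 ± 0.21. Complement C3 (2.49 ± 0.18) and Kynu, a kynurenine pathway enzyme (2.43 ± 0.08), rose as well.

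The largest fall was that of Slc22a7, an organic anion transporter, which went from 89.5 ± 23.7 to 2.19 ± 0.84 FPKM (-5.08 ± 0.12; adjusted p = 4.6e-26). Slco1a1, another one, went from 172 ± 50.3 to 7.79 ± 7.46 (-4.77 ± 0.27; adjusted p = 2.4e-16). Acsm3, a medium-chain acyl-CoA synthetase (-3.63 ± 0.14), Cyp7b1, an oxysterol hydroxylase (-3.48 ± 0.16), Slc22a26 (-3.10 ± 0.11) and Akr1c14, a hydroxysteroid dehydrogenase (-2.79 ± 0.11), fell too. So did Ldc1 (-2.73 ± 0.09), Mfsd2a, a lysophospholipid transporter (-2.67 ± 0.19), and Cpe, carboxypeptidase E (-2.60 ± 0.07). Kap, the androgen-regulated kidney protein gene, fell by 2.51 on the log2 scale; it made up 9.42 ± 1.39% of all FPKM in control and 1.75 ± 0.47% in diabetes. In all, 6668 of 11088 genes passed the test, 4868 higher and 1800 lower in diabetes, and 225 of them differed by at least 1 (111 higher, 114 lower). The split depends on the scaling: with median-ratio scaling 2973 were higher and 2905 lower, and with quantile normalization 3131 and 2868, while the median over all genes moved from 0.08 to 0.01 in both. Directions of changes smaller than about 0.08 are therefore not settled.

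**Figure D1:**
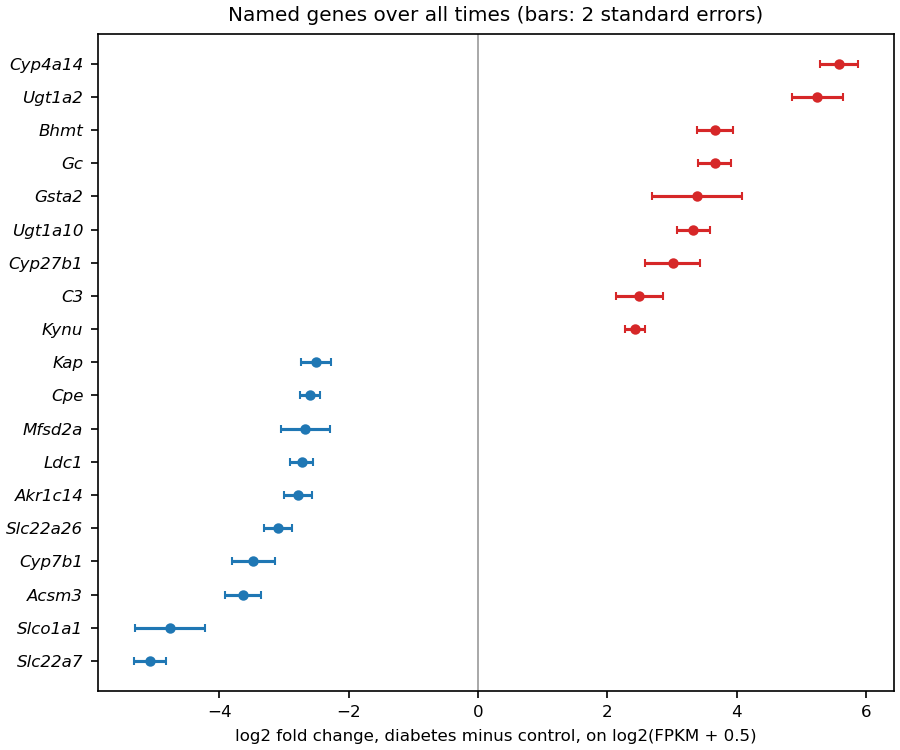
Log2 fold change (diabetes minus control, on log2(FPKM + 0.5)) of 9 of the genes with the largest rise (red) and the 10 with the largest fall (blue) over all times; points are limma estimates from 36 libraries and bars extend 2 standard errors. They range from 5.58 for Cyp4a14 to -5.08 for Slc22a7.

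Lipid and energy lists moved in both directions. Of 24 fatty acid oxidation genes 18 rose and 5 fell (median 0.20), led by Acaa2, a thiolase (1.34 ± 0.06), Hadhb (0.39 ± 0.03) and Hadha (0.41 ± 0.03), while Crot and Acads were among those that fell (-0.67 ± 0.06 and -0.28 ± 0.03). The list's camera adjusted p was 0.035 (0.68 with an estimated correlation). Of 19 PPAR-alpha targets and ketogenesis genes 15 rose and 2 fell (median 0.58; adjusted p = 0.00092, and 0.33 with an estimated correlation); the 2 that fell, Bdh1 (-1.32 ± 0.06) and Acat1 (-0.71 ± 0.03), act in ketone body metabolism. Of 24 cholesterol synthesis genes 12 fell and 3 rose (median -0.14; adjusted p = 6.4e-06, and 0.17 with an estimated correlation), with Cyp51 at -1.81 ± 0.10 and Idi1 at -1.54 ± 0.09. Of 18 fatty acid synthesis genes 7 fell and 4 rose (median -0.03; adjusted p = 0.014, and 0.25 with an estimated correlation): Me1 (-1.01 ± 0.04) and Fasn (-0.63 ± 0.06) fell, and Elovl6 (0.75 ± 0.05) and Acacb (0.48 ± 0.05) rose; under quantile normalization this list's adjusted p was 0.061. Of 23 sphingolipid and phospholipid genes 12 fell and 7 rose (median -0.07; adjusted p = 0.0018, and 0.12 with an estimated correlation), among them Cers5, a ceramide synthase (-0.59 ± 0.04).

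Of 13 gluconeogenesis genes 11 rose and 1 fell (median 0.32; adjusted p = 0.00092, and 0.045 with an estimated correlation), with Pck1 at 1370 ± 466 FPKM in control and 2742 ± 681 in diabetes (1.04 ± 0.07). Of 15 glycolysis genes 12 rose and 1 fell (median 0.24; adjusted p = 0.0019, and 0.36 with an estimated correlation), and of 30 oxidative phosphorylation genes 28 rose and 0 fell (median 0.23; adjusted p = 4.3e-07, and 0.38 with an estimated correlation), Eno1 (0.75 ± 0.03) and Atp5o (0.49 ± 0.03) in front. The lists of fatty acid uptake and triglyceride turnover and of cholesterol and lipoprotein transport did not pass (adjusted p = 0.96 and 0.90). In the first, 17 members rose and 6 fell, with a median of 0.19, a mean of -0.06 and an upward test; Acsm3, Cd36, the fatty acid translocase (-2.15 ± 0.12), and Lpl (-1.56 ± 0.07) fell and Mgll rose (0.98 ± 0.05). In the second, 7 rose and 5 fell, with a median of -0.03, a mean of 0.16 and a downward test; Apob rose by 0.90 ± 0.06.

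By median fold change, the lists of genes that depend on sex in the mouse kidney stood apart most. Of 14 androgen-responsive genes 13 fell and 1, Cyp4a12b, rose (0.96 ± 0.11), with a median of -1.70 (adjusted p = 3.5e-18, and 0.012 with an estimated correlation). Cyp4b1 went from 2399 ± 248 to 783 ± 129 FPKM and Slc7a13 fell by 1.93 on the log2 scale. Of 7 genes higher in female kidney 6 rose and 1 fell, Slco1a6 (-0.54 ± 0.05), with a median of 1.77 (adjusted p = 0.00092, and 0.12 with an estimated correlation); Prlr, the prolactin receptor, rose by 1.77 ± 0.12 and Cyp2d26 by 1.61 ± 0.06. Cyp4a14 belongs to this list and to the PPAR-alpha list.

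Markers of several nephron segments rose together. Of 10 podocyte genes 9 rose (median 0.41; adjusted p = 0.0027, and 0.37 with an estimated correlation), with Nphs1 at 0.83 ± 0.06. Of 17 genes of thick ascending limb and distal tubule 15 rose (median 0.35; adjusted p = 0.0046, and 0.37 with an estimated correlation), with Calb1 at 1.42 ± 0.08 and 1, Egf, that fell. Of 15 collecting duct genes 12 rose (median 0.37; adjusted p = 0.014, and 0.45 with an estimated correlation) and 2, Aqp4 and Fxyd4, fell. Of 27 proximal tubule transporters 14 rose and 6 fell (median 0.12; adjusted p = 0.95), Slc5a10 by 1.14 ± 0.05 and Slc22a12, the urate transporter, by -0.53 ± 0.05. Of 14 tubule injury genes 11 rose and 2 fell (median 0.43; adjusted p = 0.021, and 0.38 with an estimated correlation): Spp1, osteopontin (1.33 ± 0.06), and Fgg (1.62 ± 0.11) rose, whereas Il34 (-1.98 ± 0.09) and Vcam1 (-0.29 ± 0.06) fell. Of 14 glucocorticoid-responsive genes 10 rose and 1 fell (median 0.64; adjusted p = 0.0099, and 0.37 with an estimated correlation), among them the metallothioneins Mt1 (1.55 ± 0.08) and Mt2 (1.75 ± 0.13) and the kinase Sgk1 (1.36 ± 0.09).

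Of 15 macrophage and myeloid genes 14 fell and 0 rose (median -0.82; adjusted p = 7.8e-07, and 0.33 with an estimated correlation), with Csf1r at 15.2 ± 5.50 FPKM in control and 6.19 ± 0.96 in diabetes, and of 19 interferon response genes 12 fell and 0 rose (median -0.42; adjusted p = 4.8e-05, and 0.38 with an estimated correlation), Ifi44 by -0.56 ± 0.07. With a minimum of 5 FPKM the camera calls of interferon response (adjusted p = 0.078), glucocorticoid-responsive genes (0.078), genes higher in female kidney (0.071) and fatty acid oxidation (0.052) were lost; that of fatty acid oxidation was also lost without both libraries that stand apart (0.054). In 2 control libraries, ZT4 replicate 2 and ZT12 replicate 3, the mean of the macrophage list lay 2.42 and 1.66 above its mean over the 36 libraries. The interferon list lay 1.002 and 2.02 above its own mean in them. Both are control libraries, so their high values are part of the fall of both lists in diabetes. The size of that fall without them is not given here. Of 16 heat shock genes 7 fell and 2 rose (median -0.13; adjusted p = 0.0057, and 0.38 with an estimated correlation); those that rose, Rbm3 (0.54 ± 0.05) and Cirbp, are induced by cold. With the list fixed in advance and p adjusted over the list alone, the members passing were 18 higher and 5 lower for fatty acid oxidation, 3 and 12 for cholesterol synthesis, 0 and 15 for macrophages and 1 and 13 for androgen-responsive genes.

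The other lists did not pass camera. The clock list had 6 genes higher and 1 lower (adjusted p = 0.96), immediate early genes 7 and 0 (0.086, and 0.015 with median-ratio scaling), stromal and smooth muscle 5 and 2 (0.37), endothelial 3 and 3 (0.61), erythroid 5 and 1 (0.53), cell cycle 6 and 0 (0.36), extracellular matrix 7 and 6 (0.52), inflammatory mediators 3 and 2 (0.97), antioxidant response 11 and 6 (0.95), renin-angiotensin 4 and 2 (0.997), unfolded protein response 2 and 3 (0.20), adipocyte 2 and 1 (0.95) and adrenal cortex 0 and 2 (0.11), the values in brackets being adjusted p. Within them Ace fell by 2.03 on the log2 scale, Agt rose by 0.99 ± 0.08, Col3a1 fell by 0.72 on the log2 scale and Thbs1 rose by 0.66 ± 0.06. The endothelial, extracellular matrix and inflammatory lists had a median (0.07, 0.10 and 0.09) and mean above 0 with a downward test, the adipocyte list a median of 0.22, a mean of -0.07 and a downward test, and the renin-angiotensin list a median of 0.09, a mean of -0.02 and an upward test. By fry, 30 of 34 lists passed. It asks whether a list's members change on average, without comparing them with the other genes. With 6668 of 11088 genes past the test over all times, such a count says little about single lists.

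**Figure D2:**
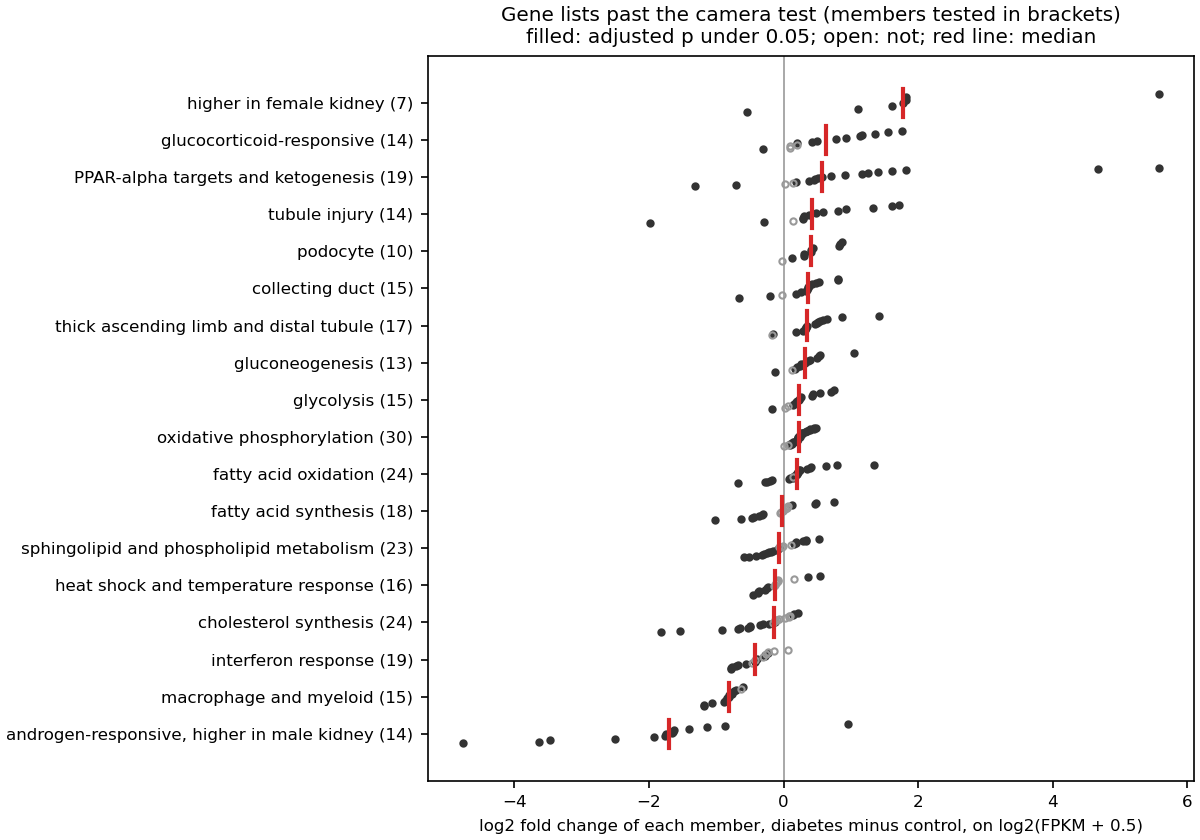
Log2 fold change of every tested member of the 18 lists past the camera test, with a preset correlation; filled points passed the test of single genes, open points did not, red lines are medians and the number of members is in brackets. Medians run from -1.70 (androgen-responsive) to 1.77 (higher in female kidney); with an estimated correlation 2 lists, androgen-responsive genes and gluconeogenesis, passed.

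The same genes led at nearly every time. Cyp4a14 and Ugt1a2 showed the 2 largest gains at ZT0, ZT8, ZT12, ZT16 and ZT20, and Cyp4a14 showed the largest at ZT4; Slc22a7 and Slco1a1 showed the 2 largest falls at all 6 times. Cyp4a14 ranged from 4.92 ± 0.34 at ZT16 to 6.24 ± 0.34 at ZT20 and Slc22a7 from -4.56 ± 0.28 at ZT12 to -5.54 ± 0.28 at ZT4 (n = 3 per group; limma adjusted p of at most 6.8e-11 in both). The genes that passed numbered 2688 at ZT0 (1909 higher, 779 lower), 2761 at ZT4 (1925 and 836), 2445 at ZT8 (1633 and 812), 2584 at ZT12 (1906 and 678), 2330 at ZT16 (1558 and 772) and 2718 at ZT20 (1902 and 816). With median-ratio scaling 1151 of 2293 were higher at ZT0, 1056 of 2288 at ZT4, 915 of 2108 at ZT8, 1103 of 2178 at ZT12, 980 of 2090 at ZT16 and 1144 of 2315 at ZT20. At all 6 times 459 genes were higher and 314 lower, and 34 genes passed with opposite signs at different times. With 1 library left out the count fell by over 1.5 times at 4 times: to 1811 at ZT4 (without Diabetes replicate 2), 1629 at ZT8 (without Diabetes replicate 3), 1565 at ZT12 (without Control replicate 3, which stands apart) and 1357 at ZT16 (without Control replicate 3). With the 6 libraries of the time alone ZT0 gave 971 and ZT4 1672.

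The second comparison asks which genes follow a 24-h rhythm in each arm. The clock list genes Dbp and Nr1d1 (REV-ERB alpha) had the largest amplitudes in both arms among genes with a mean of at least 5 FPKM. They were, for Dbp, 2.69 ± 0.12 in control and 2.61 ± 0.16 in diabetes, with peaks at 8.25 and 8.08 h, and, for Nr1d1, 2.46 ± 0.13 and 2.07 ± 0.15, with peaks at 5.33 and 4.93 h (SE, n = 18). Nfil3, Per2 and Nr1d2 followed in both arms. Igfbp1 was among the 6 largest in control (1.49 ± 0.26) and Hmox1, heme oxygenase, in diabetes (1.28 ± 0.35); the latter rests on ZT20, where the 3 libraries gave 329 ± 242 FPKM, and its call was lost without ZT20 replicate 1 or 2. A rhythm was found for 4263 genes in control (38.4%) and 3165 in diabetes (28.5%), 2193 of them in both, against 1217 for independent lists. Among the 2193 the median peak difference was -0.13 h and 84.4% peaked within 2 h. The lower count in diabetes does not go beyond exchanges of the arms within the times, of which 28 of 100, the real grouping included, gave as large a difference. The order turns with time as a 6-level factor (3025 in control, 3238 in diabetes) and with a minimum amplitude of 0.25 (966 and 1037).

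Clock genes were rhythmic in both arms for 20 of 23 members. Their median peak difference was -0.27 h, diabetes minus control (15 of 20 earlier; permutation p = 0.43, with 95% of the draws between -0.60 and 0.60 h), and it was 0.01 h without Diabetes ZT4 replicate 3. Arntl (BMAL1) peaked at 20.5 h in both arms, Per2 at 13.8 and 13.1 h and Cry1 at 16.3 and 15.4 h. No clock gene passed the permutation test of a peak or an amplitude difference after adjustment (0 of 20 and 0 of 23). The median amplitude difference was -0.02 (permutation p = 0.61). Levels over the day differed for some members: 6 were higher, 1 was lower and 16 did not pass. The list as a whole did not pass camera (adjusted p = 0.96). Per1 rose by 0.89 ± 0.14, Cry2 by 0.41 ± 0.06 and Hlf by 0.25 ± 0.04.

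**Figure D3:**
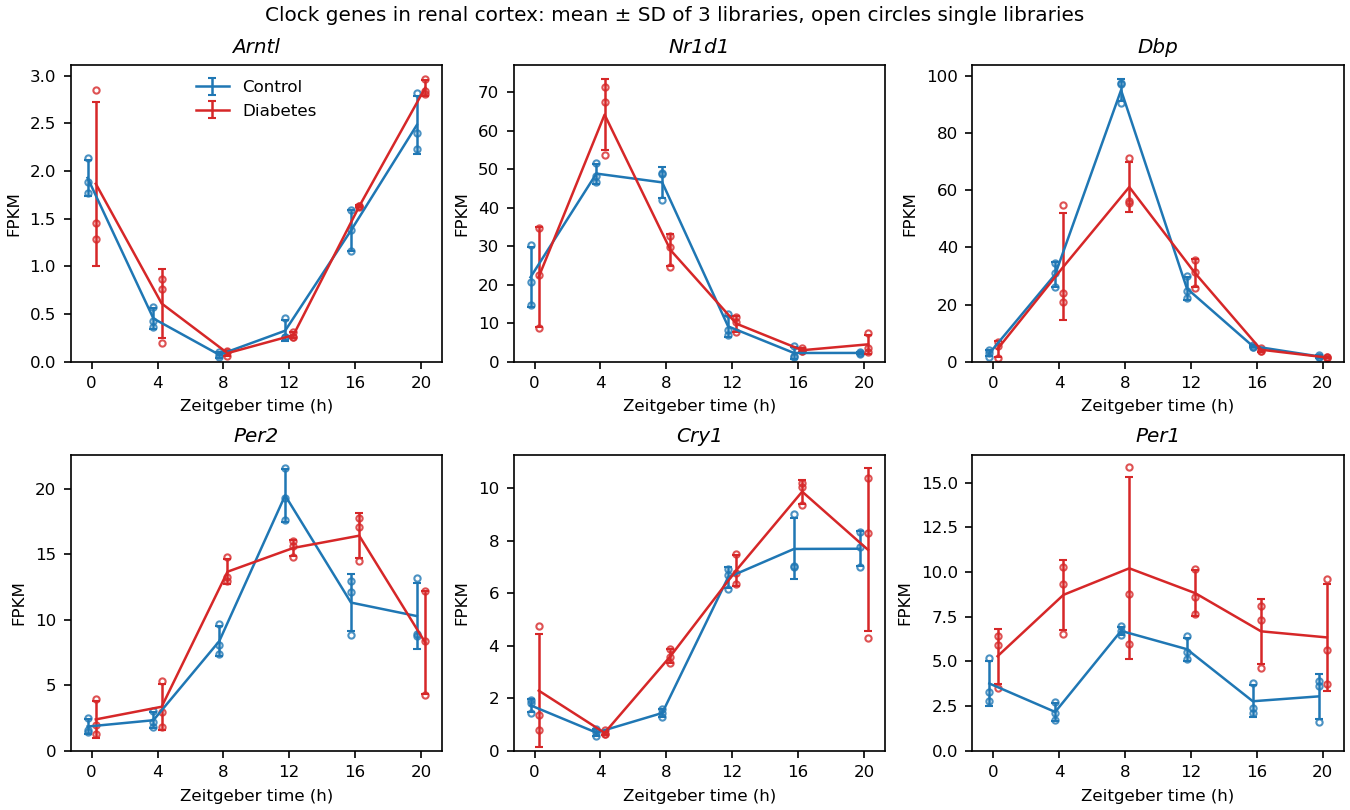
FPKM against zeitgeber time (h) for 6 clock genes; lines join group means of 3 libraries, bars are SD, open circles are single libraries, control in blue and diabetes in red. Arntl peaks at 20.5 h in both arms, and Per1 is higher in diabetes by 0.89 on the log2 scale over the day.

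Other lists differed in how often their members were rhythmic, with 12 of 102 pairs of list and gene set past Fisher's exact test. Clock genes (20 of 23 in each arm), unfolded protein response genes (14 of 16 in control, 12 of 16 in diabetes) and heat shock genes (13 and 10 of 16) were rhythmic more often than all genes, as were cholesterol synthesis genes in control (17 of 24). Oxidative phosphorylation genes were rhythmic less often (3 of 30 in control, 0 of 30 in diabetes), and so were macrophage genes in control (0 of 15). Fisher's exact test takes the members of a list as independent, which they are not. The estimated correlation was 0.74 for oxidative phosphorylation and 0.64 for macrophage genes. Of the genes with a different rhythm 2 were in the cholesterol list and 1 in the cell cycle list. Most of these calls were lost in some setting. That of cholesterol synthesis in control was lost with median-ratio scaling (adjusted p = 0.37), quantile normalization (0.24), a minimum of 5 FPKM (0.52) and in 13 of 36 omissions of 1 library. That of heat shock in control was lost with median-ratio scaling (0.12) and in 3 omissions, and that in diabetes with quantile normalization (0.052), a minimum of 5 FPKM (0.12) and in 11 omissions. With no filter the calls of oxidative phosphorylation (0.55 in control, 0.30 in diabetes) and of macrophages (0.15) were lost. Without both libraries that stand apart those of oxidative phosphorylation (0.054) and macrophages (0.855) in control were lost, and with 1 library left out they were lost in 3 and 6 of 36 omissions. With no filter the calls of a different rhythm in cholesterol synthesis and the cell cycle were lost too (adjusted p = 1 in both); with 1 library left out they were lost in 11 and 33 of 36 omissions, and the latter rests on 1 gene.

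The third comparison asks whether the rhythm itself differs between the arms. It did for 7 genes, of which 6 are described. Slc2a5, the fructose transporter, had an amplitude of 0.66 ± 0.05 in control and 0.20 ± 0.04 in diabetes (adjusted p of the difference in rhythm 0.00056). Its level was higher in diabetes at all 6 times (40.9 ± 14.2 FPKM in control and 86.7 ± 11.7 in diabetes). These amplitudes are on the log2 scale and so relative to the level. In FPKM the control group means ran from 23.4 at ZT20 to 64.1 at ZT8 (n = 3). Those of diabetes ran from 73.1 at ZT0 to 103 at ZT8 (n = 3). A difference in rhythm on the FPKM scale was not tested. Genes of sterol and fatty acid synthesis were among the others. Srebf1, the transcription factor of fatty acid synthesis, went from 8.98 FPKM at ZT8 to 18.2 at ZT20 in control (n = 3). No rhythm passed in diabetes (adjusted p = 0.34), and the difference in rhythm had an adjusted p of 0.038. Idi1, an isomerase of cholesterol synthesis, had an amplitude of 0.55 ± 0.07 in control and 0.26 ± 0.05 in diabetes, with peaks at 23.4 and 3.88 h (0.035). Pnp, a purine phosphorylase, peaked at 0.10 and 21.1 h with like amplitudes (0.29 in both; 0.038). Gpd2, a glycerol phosphate dehydrogenase, peaked at 4.29 and 16.5 h (0.038). Mcm5, a replication factor whose mean is under 5 FPKM, had an amplitude of 0.10 ± 0.08 in control and 0.71 ± 0.09 in diabetes (0.044).

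The next counts are adjusted over each list alone, with no adjustment across the lists. The rhythm differed for 12 of 24 cholesterol synthesis genes (2 over all genes). It differed for 4 of 18 fatty acid synthesis genes and 2 of 9 cell cycle genes (1 over all genes in each). In the following lists 0 members passed over all genes. The counts were 3 of 19 PPAR-alpha and ketogenesis genes, 3 of 8 erythroid genes and 2 of 24 fatty acid oxidation genes. They were 2 of 13 for gluconeogenesis, 2 of 3 for adipocyte and 1 of 28 (Acsl3) for fatty acid uptake and triglyceride turnover. Fabp4 and Lipe stand in both the adipocyte and the uptake list, and in the latter their adjusted p was 0.10. Msmo1 peaked at 22.1 h in control and 2.45 h in diabetes and Fdft1 at 0.01 and 4.77 h. Over all genes 676 had an unadjusted p under 0.05, where chance gives 554. The count of 7 is small and unsteady: leaving out 1 library gave 1 (without Control ZT8 replicate 1) to 9 (without Control ZT0 replicate 1), no filter 2, median-ratio scaling 4 and time as a 6-level factor 13, of which 3 were shared. Slc2a5 kept its call in all 36 of these omissions; Idi1 lost it in 8, Srebf1 in 20, Gpd2 in 23, Pnp in 23 and Mcm5 in 30.

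**Figure D4:**
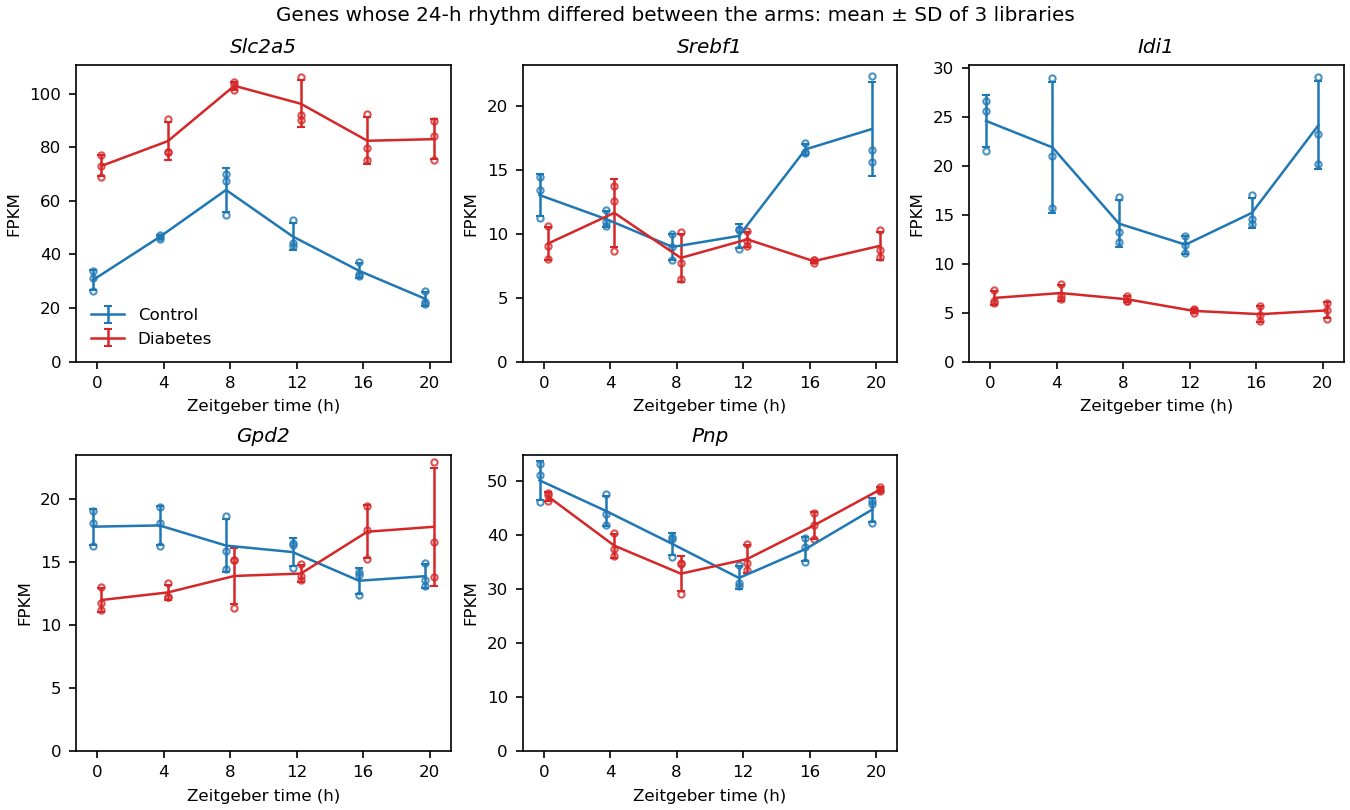
FPKM against zeitgeber time (h) for 5 genes with a mean of at least 5 FPKM whose rhythm differed between the arms; lines join group means of 3 libraries, bars are SD, open circles are single libraries, control in blue and diabetes in red. Slc2a5 lies higher in diabetes at every time, and Srebf1 in control rises from 8.98 at ZT8 to 18.2 at ZT20.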

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

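The permutation test of the mean daily profile over 34 lists was devised after the peaks of single genes, Srebf1 and Idi1 among them, had been seen, and the test of a shifted clock after its result was known; the omission of single libraries was set before its result was seen.

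The rhythm of 7 genes differed between the arms by the test of the interaction itself (limma adjusted p), among them Slc2a5 (0.00056), Idi1 (0.035), Srebf1 (0.038), Pnp (0.038), Gpd2 (0.038) and Mcm5 (0.044). None of the exchanges of arms within the times gave as many: 1 of 100 splits, the real one, reached 7, and the highest of the others was 0. Any count above 0 would have stood out. The splits argue against chance for some difference in rhythm, not for the number 7 or for each gene. The mean daily profile of 2 lists also differed, after adjustment over 34 lists: cholesterol synthesis (permutation p = 1e-04, adjusted p = 0.0017) and fatty acid uptake and triglyceride turnover (permutation p = 1e-05, the smallest the draws can give, adjusted p = 0.00034). For fatty acid synthesis the adjusted p was 0.14.

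The mean of the 24 cholesterol synthesis genes peaked at 22.8 h in control and 4.27 h in diabetes, and that of the 28 genes of fatty acid uptake and triglyceride turnover at 6.83 and 14.4 h; the amplitudes of these means are small (0.14 and 0.16 for cholesterol synthesis, 0.057 and 0.078 for uptake and turnover, log2), and of the single members 12 of 24 and 1 of 28 differed in rhythm when adjusted over the list alone. A shift of the kidney clock as a whole is not borne out. The clock list's median peak difference was -0.27 h, opposite in sign to both lists. It was far from the 5.52 and 7.60 h between the peaks of their mean curves. Those hours belong to the means, not to each member. Of the uptake and turnover genes rhythmic in both arms, Dgat2 moved most, from 9.09 h in control to 11.7 h in diabetes. The permutation test compared amplitude and peak of the means together, not a shift alone. Nor did a single library carry the difference, since the highest permutation p with any 1 library left out was 0.00060. A changed time of feeding in db/db mice, which are hyperphagic, may be behind both profiles, and so may a change in insulin or sterol signalling; food intake was not analysed here, and both stay open as hypotheses that belong to the arm the design names. The members moved by different amounts and some, such as Mvd, had a rhythm in control and none past the threshold in diabetes; a shift of a single shared signal was not tested.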

How the results depend on the processing

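All settings were planned except the one without both libraries that stand apart (Control ZT4 replicate 2 and Control ZT12 replicate 3), chosen after seeing the data. Of 13 main results, 13 stayed within 1.5 times under both pseudocounts, the minimum of 5 FPKM and quantile normalization, although single lists lost their call under the last 2 (values in the report). Where a value moved, the cause was not tested unless the setting itself removes genes or libraries. Depth limits values far below 1 FPKM, which rest on few fragments, also where the gene's mean passes the filter.

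The added minimum log2 fold change of 1 left 225 genes over all times and 270, 311, 232, 217, 245 and 275 at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, by construction. Array weights, whose fit did not fully converge, gave 4345 at ZT0, 3970 at ZT8 and 3971 at ZT12; the 6 libraries of the time alone gave 971 at ZT0 and 1672 at ZT4; without both libraries that stand apart ZT12 had 1653. A minimum amplitude of 0.25 left 966 rhythmic genes in control and 1037 in diabetes. The difference in rhythm had 2 genes with no filter, 4 with median-ratio scaling and 13 with time as a 6-level factor. An estimated correlation left 2 lists.

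The replicate numbers do not pair the libraries: over 18 pairs of the same number and time the correlation of deviations ran from -0.30 to 0.38, with 2 over 0.1 and 2 libraries closest to their own number. With the replicate block the difference in rhythm had 2 genes, all times 6413 and the lists 18, and the share of cell cycle genes with a different rhythm had an adjusted p of 1.

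The amplitude difference of Pnp (-0.0033) changed sign with median-ratio scaling (0.0074), quantile normalization (0.015) and without both libraries that stand apart (0.014), and ran from -0.026 to 0.013 with 1 library left out. The adjusted p of the share of genes with a different rhythm was 1 with no filter for cholesterol synthesis and for the cell cycle, and 1 with median-ratio scaling for the latter; with 1 library left out it ran from 0.00046 to 1 and from 0.023 to 1. That of macrophage genes rhythmic in control was 0.855 without both libraries.

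Leaving out 1 library gave 6466 to 6701 genes over all times, 1827 to 2935 at ZT0, 1811 (without Diabetes replicate 2) to 2474 at ZT4, 1629 (without Diabetes replicate 3) to 2171 at ZT8, 1565 (without Control replicate 3; 1720 without Diabetes replicate 1) to 2370 at ZT12, 1357 (without Control replicate 3; 1454 without Diabetes replicate 3) to 2048 at ZT16 and 1814 to 2719 at ZT20. Rhythmic genes numbered 3549 to 4392 in control and 2645 to 3326 in diabetes, lists 17 to 19, and list shares 5 (without Control ZT12 replicate 2) to 13, with 7 without Control ZT4 replicate 1 or Control ZT20 replicate 2 or 3. The difference in rhythm had 1 to 9 genes and moved by over 1.5 times in 20 of 36 omissions: to 1 without Control ZT8 replicate 1 or 2, Control ZT12 replicate 2, Control ZT20 replicate 2 or 3, Diabetes ZT8 replicate 3 or Diabetes ZT20 replicate 1; to 2 without Control ZT4 replicate 3, Control ZT8 replicate 3, Control ZT16 replicate 2 or 3, Diabetes ZT0 replicate 2, Diabetes ZT4 replicate 1 or 2 or Diabetes ZT20 replicate 3; to 3 without Diabetes ZT16 replicate 1 or 2; and to 4 without Control ZT4 replicate 2, Control ZT20 replicate 1 or Diabetes ZT20 replicate 2. The median clock peak difference ran from -0.37 to 0.0075 h, its sign changing without Diabetes ZT4 replicate 3. Of the single genes and lists, 246 values lost their call, 48 changed sign (42 of them also lost the call) and 29 gained a call, against 12175 with the same call and sign.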

Other observations

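Except for the noise added to the control values, which was set before its result was seen, the tests in this part, their bounds and the limit for libraries that stand apart were chosen after the results were seen.

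The androgen-responsive genes fell in diabetes by a median of 1.70 on the log2 scale. Female or mislabelled animals are argued against by 4 Y-linked genes, whose sum in the lowest diabetes library was 0.855 of the control mean (sums of 23.7 ± 2.02 FPKM in control and 24.97 ± 3.22 in diabetes, n = 18 per arm). Fewer proximal tubule cells as a whole are argued against by the proximal tubule transporters, with a median of 0.12. That list was not split by segment of the proximal tubule, so a loss of 1 segment alone was not tested. The share that Kap takes of the libraries is argued against by median-ratio scaling, which left the median of the androgen-responsive genes at -1.78. Lower androgen action in db/db males may account for the fall, as a hypothesis found and tested on the same data; hormone levels were not analysed here.

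Fewer genes were rhythmic in diabetes (3165) than in control (4263); with the arm means removed first, as in the exchanges, the difference was 1084. Chance cannot be excluded: 28 of 100 exchanges of the arms within the times, the real grouping included, gave as large a difference, the largest other being 2355. The residual variance was larger in diabetes for 70.0% of genes, with a median ratio of 1.36, and noise of that size added to the control values left a median of 3174.5 rhythmic genes (3074 to 3234 in 100 draws); 39 draws were at or under 3165, between the bounds of 50 and 5 set for this test, so a larger spread may account for the difference but this is not settled. Lower amplitudes stay open too, since the mean squared amplitude in diabetes was 1.004 times that in control, inside the range with arms exchanged (0.615 to 1.36). A difference in rhythm between the genotypes stays open.

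The gene for ribosomal protein S18, Rps18, in the major histocompatibility region of chromosome 17, varied widely between libraries of the same group. It stood at 23.1 to 41.9 FPKM in 19 libraries and at 65.2 to 281 in the other 17, of which 11 were control and 6 diabetes libraries; the control libraries at ZT0 gave 103, 153 and 160 FPKM and the diabetes libraries at ZT0 41.9, 37.5 and 281. Of the 20 genes that followed Rps18 most closely within groups, 11 lie on chromosome 17 in GRCm38.p6, which holds 4.96% of the tested genes (Fisher's exact test over genes, which are not independent, p = 4.5e-10), among them H2-K1, H2-T22, H2-Q7, Ppt2, Wiz and Nelfe. These values suggest a stretch of chromosome 17 that differs between animals of both arms, as a hypothesis. Inflammation in some animals was counted against it through 1 of the 20 genes in the macrophage or interferon lists or in class II (H2-DMb1), but 5 of the 20 are H2 genes and the class I members, which inflammation can raise, were not in that count, so this argues only weakly.

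A similar question for chromosome 4, where Lepr lies, came out negative. In a window of 33 tested genes that holds the place of Lepr 6 (18.2%) passed with a log2 fold change of at least 0.5, against 8.04% of all tested genes, and 7.98% of 10431 windows of 33 genes had as large a share. This measure was the second of 2 tried: by the first, an adjusted p under 1e-08, 7 of the 33 passed and 6.87% of windows had as large a share. Neither puts the region in the top 5%, the bound used, so a linked segment may exist but is not shown.

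Other groupings of the libraries bear on the counts of the report. For all times the real grouping gave 6668 genes and the highest of the others 64 (1 of 100 splits, the real one, as large); for rhythm in control 4263 and 175, for rhythm in diabetes 3165 and 3, and for list shares 12 and 2 (1 of 100 each); for the lists 18 and 18 (2 of 100). A share of 1 of 100, the smallest these splits can give, argues against chance for the first 3 of these counts. For the list shares the splits cannot decide. Exchanging the times also removed nearly all rhythmic genes (at most 175 left in control and 3 in diabetes), so few were left to fall in any list. For the lists the share of 2 of 100 is under the bound of 5, but 1 other grouping called as many lists as the real one, and with an estimated correlation 2 lists passed, so that this count stands on weaker ground. At single times 6 libraries give 10 splits, too few for a share under 0.05; the real and the highest other counts were 2688 and 1830 at ZT0, 2761 and 0 at ZT4, 2445 and 0 at ZT8, 2584 and 0 at ZT12, 2330 and 1 at ZT16 and 2718 and 4 at ZT20. The 1830 genes at ZT0 parted Control replicate 1 and Diabetes replicates 1 and 3 from the rest, which points to a structure of the samples at that time other than the arm.

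By the root mean square of their deviations from the group means, 2 libraries stood over 1.5 times the median: Control ZT4 replicate 2 (1.56) and Control ZT12 replicate 3 (1.54). The next, Diabetes ZT0 replicate 3, stood at 1.43, and the limit of 1.5 was set after these values were seen. In the first the macrophage list lay 2.42 and the interferon list 1.002 above their means, and in the second 1.66 and 2.02.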
